A study of Homo sapiens with 21 samples.

How the data were processed

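The series measured messenger RNA of MV4-11 cells in 21 libraries, in 7 groups of 3. Per the submitters' processing notes, total RNA was isolated with Qiagen RNeasy, libraries were made with the Lexogen QuantSeq 3′ kit, reads were split by sample with bcl2fastq 2.20.0.422, aligned with HISAT2 to hg19 and counted per gene with HTSeq. The values are raw read counts per Ensembl gene as deposited, with no normalization per the labels. The strand setting of the counting is not stated, so antisense and overlapping genes are uncertain. The table held 54042 genes, of which 51854 matched a symbol in the reference table and 2188, with 8 counts in all, did not. The annotation at hand was GENCODE 29 on GRCh38, which differs from the build of the files, so it served only for names, GC content and length, and no coordinates are given.

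Counts were tested in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with TMM size factors, filterByExpr by group (minimum count 10, minimum total 15), which kept 11610 genes, and 1 quasi-likelihood fit of all 21 libraries with a mean per group (common biological coefficient of variation 0.149). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The 9 comparisons were wild type at 6 h and at 24 h against DMSO, 24 h against 6 h, each knockout at 24 h against its DMSO, each knockout against wild type in DMSO, and the difference between the 24 h response of each knockout and that of wild type. Genes with 3 or fewer counts over a group are given as a ratio of counts with an exact 95% interval, or as a floor where the group had 0 counts, set at 3 counts. Such intervals and floors cover counting error only. Figures were drawn with matplotlib 3.10.9, and tables prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.

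The 45 gene lists were fixed before the data were examined, as were the comparisons and the settings to vary. They covered iron, heme and dioxygenases, stress responses, mitochondria, carbon and lipid metabolism, ribosomes, MYC, ferroptosis, metallothioneins, lysosome and autophagy, cell death and p53, cell cycle, inflammation and interferon, heat shock, immediate early genes, lineage and leukaemia markers, and nuclear RNAs. Lists with at least 3 tested members went through camera, a test of direction that allows for correlated genes, with a preset correlation of 0.01 and adjustment over the lists of a comparison. Members were counted by the gene test over all genes and adjusted over the list alone.

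Named genes were set by a rule: HK2 and PGP in every library; for each list described, called members in order of adjusted p (up to 4, of which the first 1 or 2 are printed), or those with the highest mean where none was called; the 8 largest rises and 8 largest falls at 6 h, at 24 h and for each knockout in DMSO, and 5 and 5 elsewhere, among called genes with a mean of at least 5 CPM over the compared groups, whose libraries did not overlap; and TFRC, FTH1, DDIT3, ATF3, BAX, BAK1, BCL2 and MCL1. A first draft had passed over list members whose call did not hold on leaving out a library, and the printed choice follows the order of adjusted p instead. Values of 2 genes that the rule would name are not reported here.

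Results were recomputed with RLE size factors, no low-count filter, DESeq2 1.42.0, the replicate number as a block, a fit of the compared groups alone, each library left out in turn, and an estimated correlation in camera. The labels do not say what the replicate numbers mark. Between DMSO and 24 h in the PGP knockout, the deviations of same-numbered libraries from their group means correlated at 0.243, 0.164 and 0.247, each over 0.1, so there the numbers were taken to pair the libraries, on the data alone, and block values stand beside the calls they change. An offset for GC content of the last 300 bases and length was added after the data were seen. The pipeline was tested on simulated data with 200 changed genes per comparison: of 50 genes changed 4-fold it recovered 43 at 24 h in wild type and 39 for the HK2 difference in response, with 8 and 4 false calls.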

Results

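Transcript ends were counted in 21 libraries of MV4-11 cells, a human leukaemia line with B-lymphoid and myelomonocytic features that carries a KMT2A rearrangement. The cells were wild type, or carried a CRISPR knockout of HK2 (hexokinase 2, which phosphorylates glucose) or of PGP (phosphoglycolate phosphatase, which removes side products of glycolysis). Wild type cells received the solvent DMSO, or ironomycin, a small molecule derived from salinomycin and also called AM5, for 6 h or 24 h. Each knockout received DMSO or ironomycin for 24 h. The labels give no time for DMSO, so time in culture may add to any change given for ironomycin. The comparison of 24 h with 6 h has no DMSO pair. Total counts lay between 3829274 and 6069264 per library (median 4823817), where 3 counts corresponded to 0.494 to 0.783 CPM (counts scaled to library size). The series title concerns mitochondrial iron and a form of cell death that needs BAX or BAK. The comparisons ask which transcripts changed under ironomycin, and whether the knockouts differed from wild type in DMSO or in the response. Fold changes are log2 values ± SE, levels are CPM as mean ± SD, and n = 3 libraries per group throughout. The examples of a list are its called members with the smallest adjusted p, or its members with the highest mean where none was called. The largest rises and falls are those among called genes with a mean of at least 5 CPM over the compared groups and no overlap between their libraries. The labels do not say that the replicates came from separate cultures, so p-values measure only the spread between these samples.

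**Figure D1:**
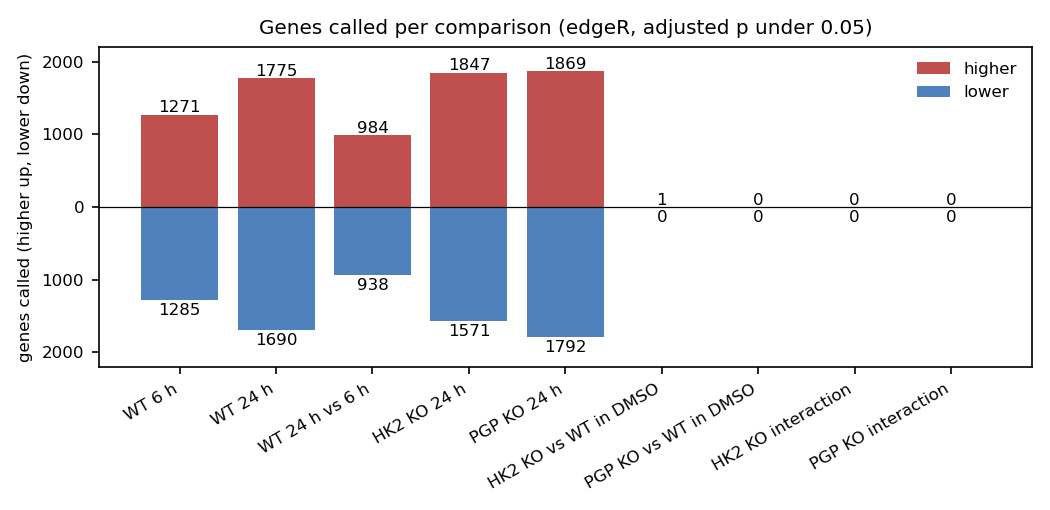
Number of genes called in each of the 9 comparisons (bars, higher above 0 and lower below 0; edgeR quasi-likelihood test, 11610 genes tested). Against DMSO, 2556 genes were called at 6 h and 3465 at 24 h in wild type cells, while the knockouts in DMSO differed from wild type in 1 and 0 genes.

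The targeted transcripts were not lost in the knockouts. HK2 (ENSG00000159399) stood at 52.6 ± 14.7 CPM in wild type DMSO, 27.4 ± 14.8 at 6 h and 45.0 ± 8.85 at 24 h, against 22 ± 2.49 and 17.9 ± 3.88 in the HK2 knockout in DMSO and at 24 h, and 43.1 ± 6.24 and 36.4 ± 4.96 in the PGP knockout. The HK2 difference between the HK2 knockout and wild type in DMSO was -1.27 ± 0.28 (edgeR adjusted p = 0.121), which is not a call. It was a call in a fit of the compared groups alone (edgeR adjusted p = 0.00987), with no low-count filter (8.7e-10) and DESeq2 (0.0115). PGP (ENSG00000184207) stood at 90.6 ± 4.49 CPM in wild type DMSO, 53.3 ± 9.31 at 6 h and 78.7 ± 5.06 at 24 h, at 75.4 ± 7.10 and 59.7 ± 5.67 in the PGP knockout in DMSO and at 24 h, and at 95.1 ± 8.33 and 81.1 ± 5.13 in the HK2 knockout. The PGP difference between the PGP knockout and wild type in DMSO was -0.26 ± 0.12 (edgeR adjusted p = 0.879). The labels do not give the edited sites, and an edit need not change the level of a 3′ tag, so these levels check neither knockout. At 6 h PGP fell in wild type cells (-0.76 ± 0.12, edgeR adjusted p = 1.2e-04), and HK2 also fell (-0.94 ± 0.28, edgeR adjusted p = 0.0181). The HK2 call was lost without wild type DMSO replicate 3 (edgeR adjusted p = 0.123), without 6 h replicate 2 (0.0587) and in the fit of the compared groups alone (0.154).

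Replicates of a group lay close together apart from replicate 2 of wild type at 6 h. Across the tested genes, the SD of the deviation from the mean of the other 2 libraries of the group was 0.675 (log2) for this library, against 0.332 to 0.480 for the other libraries. On the second principal component, which held 15% of the variance, it stood at −71.7 while replicates 1 and 3 of its group stood at −17.7 and −13.5. The deviation of each gene list in this library, as the log2 difference from the mean of replicates 1 and 3, is therefore given beside the 6 h results.

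At 6 h of ironomycin, targets of the integrated stress response rose and chaperones fell in wild type cells. TRIB3, a pseudokinase induced by ATF4 and CHOP, went from 19.5 ± 6.17 to 287 ± 46.8 CPM (3.87 ± 0.24), and DDIT3, which encodes CHOP, from 6.98 ± 0.938 to 54.3 ± 12.2 CPM (2.96 ± 0.21). HSPA8, the constitutive HSP70 chaperone, fell from 821 ± 187 to 129.8 ± 78.7 CPM (-2.66 ± 0.35). In all, 2556 of 11610 genes were called, 1271 higher and 1285 lower, and 672 of them changed at least 2-fold (edgeR quasi-likelihood test). Without replicate 2 the count was 2145, and in a fit of the 6 h and DMSO groups alone it was 1212. Besides TRIB3 the largest rises among genes of at least 5 CPM were MT-TL1, the mitochondrial leucine tRNA (4.72 ± 0.25), NLRP12 (4.38 ± 0.46), NUPR1 (4.27 ± 0.35), IFIT3 (4.21 ± 0.68), INHBE (4.03 ± 0.35), ADM2 (4.0 ± 0.30) and ORM1 (3.86 ± 0.55). IFIT3 stood at 3.27 without 6 h replicate 1, and NLRP12 at 5.04 without DMSO replicate 3. The largest falls after HSPA8 were HPDL (-2.62 ± 0.27), HSPA1B (-2.59 ± 0.25), PNP (-2.19 ± 0.48), RPP25 (-2.04 ± 0.35), DNAJA1 (-1.98 ± 0.15), MNDA (-1.80 ± 0.30) and PPARGC1B (-1.72 ± 0.25). The PNP call was lost in the fit of the 6 h and DMSO groups alone (edgeR adjusted p = 0.0568). HSPA1B has a near-identical copy, HSPA1A, so its reads may be split between them.

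Of the targets of ATF4 and CHOP, the transcription factors of the integrated stress response, 25 of 27 measured members rose, 0 fell and 2 were not called (25 and 0 adjusted over the list alone, camera adjusted p = 8.3e-44). ATF5 (2.43 ± 0.15) and TRIB3 (3.87 ± 0.24) rose, and replicate 2 deviated by 0.05 for this list. Among cytosolic aminoacyl-tRNA synthetases, 11 rose, 1 fell and 8 were not called (list alone 11 and 1, camera adjusted p = 2.8e-07). CARS1 (1.75 ± 0.12) and GARS1 (1.17 ± 0.12) rose, and replicate 2 deviated by 0.21. Enzymes of serine, glycine, proline and one-carbon synthesis moved mostly the same way: 11 rose, 4 fell and 5 were not called (list alone 11 and 4, camera adjusted p = 4.5e-06). PCK2 (2.62 ± 0.23) and PSPH (1.6 ± 0.17) rose, and replicate 2 deviated by 0.01. For autophagy, 10 rose, 1 fell and 16 were not called (list alone 10 and 1, camera adjusted p = 0.00302). MAP1LC3B (1.01 ± 0.14) and NBR1 (0.82 ± 0.12) rose, and replicate 2 deviated by 0.02. ATF3, a stress-induced transcription factor, rose by 2.23 ± 0.30. Among the markers set for iron and death, TFRC stood at 0.02 ± 0.16 (edgeR adjusted p = 0.946), BAX at -0.12 ± 0.19 (0.678), BAK1 at 0.15 ± 0.22 (0.666), BCL2 at 0.29 ± 0.12 (0.0884) and MCL1 at -0.35 ± 0.16 (0.130). Without 6 h replicate 3, BCL2 stood at 0.393 (edgeR adjusted p = 0.0332) and MCL1 at -0.488 (0.0465), both past the threshold. The signs of TFRC and BAX depended on single libraries, with TFRC between -0.0787 and 0.198 and BAX between -0.305 and 0.0193 on leaving out 1 library. Ferritin heavy chain FTH1 was below the low-count filter, which need not mean low mRNA.

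Chaperones and growth genes moved the other way at 6 h. Of heat shock genes, 1 of 22 members rose, 15 fell and 6 were not called (list alone 1 and 15, camera adjusted p = 1.5e-13). DNAJA1 (-1.98 ± 0.15) and HSPH1 (-1.37 ± 0.12) fell, and replicate 2 deviated by -0.03. For MYC and nucleolar ribosome biogenesis genes, 0 rose, 21 fell and 12 were not called (list alone 0 and 27, camera adjusted p = 5.9e-12). NOP16 (-1.34 ± 0.14) and NIP7 (-0.96 ± 0.12) fell, and replicate 2 deviated by -0.01. Of mitochondrial ribosomal proteins, 0 rose, 29 fell and 42 were not called (list alone 1 and 33, camera adjusted p = 1.3e-09). MRPS6 (-0.95 ± 0.11) and MRPL44 (-1.02 ± 0.13) fell, and replicate 2 deviated by -0.04. Of DNA replication and G1/S genes, 0 rose, 22 fell and 21 were not called (list alone 0 and 25, camera adjusted p = 4.5e-09, adjusted p = 0.246 with an estimated correlation). FEN1 (-1.67 ± 0.16) and CDC6 (-1.22 ± 0.18) fell, and replicate 2 deviated by -0.12. For the endoplasmic reticulum unfolded protein response, 1 rose, 9 fell and 16 were not called (list alone 2 and 11, camera adjusted p = 0.0172, adjusted p = 0.267 with an estimated correlation). MANF (-1.62 ± 0.23) and CRELD2 (-0.87 ± 0.15) fell. Replicate 2 deviated by -0.20 for that list, and its call was lost without that library (camera adjusted p = 0.0619).

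Nuclear genes of the respiratory chain fell and inflammatory genes rose at 6 h, in calls that an estimated correlation did not keep. In complexes II to V, 0 rose, 11 fell and 28 were not called (list alone 0 and 12, camera adjusted p = 1.9e-05, adjusted p = 0.267 with an estimated correlation). CYCS (-0.94 ± 0.14) and ATP5MC1 (-0.76 ± 0.12) fell, and replicate 2 deviated by -0.03. In complex I, 1 rose, 12 fell and 23 were not called (list alone 2 and 13, camera adjusted p = 0.00247, adjusted p = 0.267 with an estimated correlation). NDUFS5 (-0.61 ± 0.11) and NDUFAB1 (-0.60 ± 0.11) fell, and replicate 2 deviated by 0.07. For inflammatory and NF-kB targets, 7 rose, 0 fell and 9 were not called (list alone 7 and 0, camera adjusted p = 5.5e-05, adjusted p = 0.246 with an estimated correlation). ICAM1 (3.74 ± 0.56) and RELB (1.71 ± 0.26) rose, and replicate 2 deviated by 0.27. For interferon-stimulated genes, 7 rose, 0 fell and 21 were not called (list alone 8 and 0, camera adjusted p = 7.6e-05, adjusted p = 0.445 with an estimated correlation). XAF1 (2.01 ± 0.18) and STAT2 (1.61 ± 0.17) rose, and replicate 2 deviated by -0.07. ICAM1 stood at 7.71 without DMSO replicate 3. KLHDC7B had 0 counts in DMSO and was at least 23.5-fold higher at 6 h, against a floor of 3 counts over the group. Of the 13 lists called at 6 h, 7 held with an estimated correlation: the integrated stress response, heat shock, MYC, mitochondrial ribosome, tRNA synthetase, serine and autophagy lists.

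Transcripts of the mitochondrial chromosome went both ways. At 6 h the transfer RNAs MT-TF (3.24 ± 0.23), MT-TV (3.54 ± 0.43), MT-TC (2.87 ± 0.29) and MT-TM (2.02 ± 0.32) rose with MT-TL1, whereas MT-TY (-1.07 ± 0.26) and MT-TP (-0.46 ± 0.14) fell. Of the ribosomal RNAs, MT-RNR1 rose (1.85 ± 0.12), and MT-RNR2, with the higher counts, was not called (0.48 ± 0.18, edgeR adjusted p = 0.0628) but passed in a fit of both groups alone (0.0471) and with no low-count filter (4.0e-04). The MT-TP call was lost without any 1 of 4 libraries (edgeR adjusted p up to 0.126) and in a fit of both groups alone (0.0902). Of the mitochondrially encoded mRNAs, 4 of 13 members rose, 5 fell and 4 were not called (list alone 4 and 5, camera adjusted p = 0.929), and their median (-0.37) and the direction of the list test (up) differed in sign. MT-ND6 (1.68 ± 0.14), MT-ND5 (1.53 ± 0.15) and MT-CO1 (1.26 ± 0.14) rose, while MT-ND3 (-1.66 ± 0.21), MT-CO2 (-1.45 ± 0.24) and MT-ATP6 (-1.02 ± 0.21) fell. Replicate 2 deviated by 0.39 for these mRNAs, 12 of them higher in it than in replicates 1 and 3. By 24 h the falls were larger and wider: 2 rose, 10 fell and 1 was not called (list alone 2 and 10, camera adjusted p = 3.6e-06, adjusted p = 0.195 with an estimated correlation). MT-CO2 (-2.23 ± 0.25), MT-CO3 (-2.13 ± 0.22) and MT-ATP6 (-2.05 ± 0.21) fell, while MT-TL1 was still higher (2.54 ± 0.23). The share of counts in these mRNAs was 5.72% ± 1.02 in DMSO, 3.97% ± 0.818 at 6 h and 2.36% ± 0.504 at 24 h, and that of MALAT1, a nuclear RNA, was 0.254% ± 0.065, 0.344% ± 0.101 and 0.646% ± 0.0993. In DMSO and at 24 h, the share of MALAT1 was 0.341% ± 0.0287 and 0.565% ± 0.102 in the HK2 knockout and 0.271% ± 0.0485 and 0.667% ± 0.270 in the PGP knockout. The transfer and ribosomal RNAs other than MT-TL1 at 6 h, and MT-CO2 and MT-ATP6 at 6 h, were chosen after their values were seen. Genes of this chromosome overlap and lie on both strands, and the strand setting of the counting is not stated, so MT-ND6, MT-TC, MT-TY and MT-TP are uncertain.

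**Figure D2:**
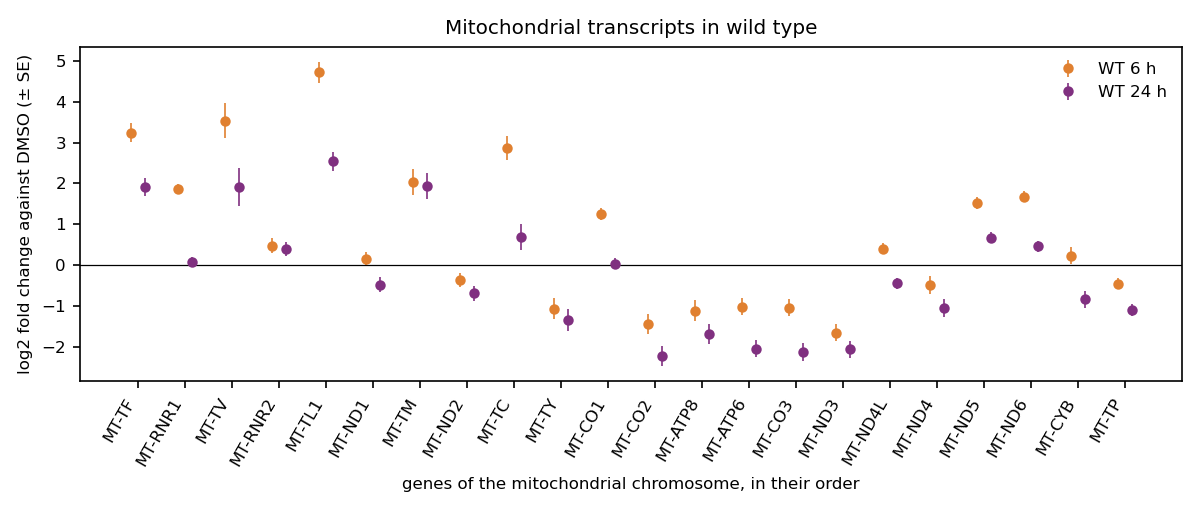
Log2 fold change against DMSO (points, bars ± SE) of each mitochondrial gene tested, in the order of the chromosome, at 6 h and 24 h of ironomycin in wild type cells (n = 3 per group). At 6 h MT-TL1 rose by 4.72 and MT-CO2 fell by 1.45, and at 24 h MT-CO2 fell by 2.23.

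At 24 h, genes of mitosis fell and genes of cholesterol synthesis rose in wild type cells, beside a strong rise of interferon-stimulated genes. CCNB1, the mitotic cyclin B1, fell from 131 ± 10.1 to 28.2 ± 5.30 CPM (-2.21 ± 0.15), and MSMO1, a sterol demethylating oxidase, rose from 11.0 ± 2.27 to 102 ± 21 CPM (3.20 ± 0.19). STAT2, which carries type I interferon signals, rose from 13.4 ± 3.03 to 64.1 ± 4.04 CPM (2.25 ± 0.16). In all, 3465 of 11610 genes were called, 1775 higher and 1690 lower, and 1121 changed at least 2-fold (edgeR). Relative to floors of 3 counts over the DMSO group, which had 0 counts, IFI44L was at least 140-fold higher, IFI27 at least 118-fold, KLHDC7B at least 64.6-fold and SIGLEC1 at least 56.3-fold. Without 24 h replicate 1 the floors gave 86.3 for IFI44L, 64.4 for IFI27 and 23.5 for SIGLEC1. IFIT1 and EPSTI1 had 1 count each in DMSO, and their ratios were 209.5 (95% interval 37.2 to 8314) and 188 (33.3 to 7453). CXCL10, with 3 counts, had a ratio of 60.8 (20.5 to 298) and a fitted log2 value of 8.81 without DMSO replicate 3, and IFIT3 rose by 5.55 ± 0.64. The largest falls, apart from the pseudogenes GAPDHP1 and MTCO2P12 which share sequence with GAPDH and MT-CO2 and are uncertain, were IGLL1 (-3.61 ± 0.37), CDC20 (-2.26 ± 0.23), SVIP (-2.25 ± 0.40), MT-CO2, CCNB1 and KIF20A (-2.20 ± 0.20).

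Cell cycle genes fell as a body at 24 h. Of G2/M and mitosis genes, 0 of 34 members rose, 34 fell and 0 were not called (list alone 0 and 34, camera adjusted p = 3.3e-64). CCNB1 (-2.21 ± 0.15) and UBE2C (-1.77 ± 0.12) fell. For DNA replication and G1/S, 0 rose, 39 fell and 4 were not called (list alone 0 and 42, camera adjusted p = 3.9e-24). MCM7 (-1.26 ± 0.11) and RRM1 (-1.16 ± 0.12) fell. For MYC and nucleolar genes, 0 rose, 26 fell and 7 were not called (list alone 0 and 30, camera adjusted p = 5.7e-12). UTP20 (-1.24 ± 0.12) and PA2G4 (-0.77 ± 0.08) fell. For mitochondrial ribosomal proteins, 0 rose, 36 fell and 35 were not called (list alone 0 and 43, camera adjusted p = 5.5e-10). MRPL44 (-1.17 ± 0.14) and MRPS34 (-0.66 ± 0.10) fell. For heat shock genes, 1 rose, 15 fell and 6 were not called (list alone 2 and 16, camera adjusted p = 6.8e-11). HSPH1 (-1.53 ± 0.12) and HSP90AA1 (-1.14 ± 0.10) fell. In complexes II to V, 0 rose, 31 fell and 8 were not called (list alone 0 and 32, camera adjusted p = 3.8e-10, adjusted p = 0.0797 with an estimated correlation). COX7B (-0.87 ± 0.12) and ATP5PF (-0.70 ± 0.10) fell. In complex I, 0 rose, 20 fell and 16 were not called (list alone 0 and 23, camera adjusted p = 3.5e-06, adjusted p = 0.0605 with an estimated correlation). NDUFS5 (-0.99 ± 0.11) and NDUFS6 (-0.69 ± 0.12) fell.

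Sterol and lipid genes, interferon-stimulated genes and antioxidant genes rose at 24 h. For cholesterol synthesis and uptake, 21 of 23 members rose, 0 fell and 2 were not called (list alone 21 and 0, camera adjusted p = 1.4e-33). MSMO1 (3.20 ± 0.19) and FDFT1 (1.73 ± 0.12) rose. For fatty acid synthesis and desaturation, 11 rose, 0 fell and 2 were not called (list alone 11 and 0, camera adjusted p = 5.9e-10). PNPLA3 (2.97 ± 0.23) and ACSS2 (1.90 ± 0.22) rose. For interferon-stimulated genes, 26 rose, 0 fell and 2 were not called (list alone 28 and 0, camera adjusted p = 5.5e-25), with a median log2 fold change of 3.04 that was the same with the 2 members at 0 counts set at their floor. XAF1 (2.87 ± 0.19) and STAT2 (2.25 ± 0.16) rose. For targets of NRF2, the regulator of antioxidant genes, 14 rose, 0 fell and 8 were not called (list alone 14 and 0, camera adjusted p = 1.9e-09). NQO1 (1.96 ± 0.17) and PGD (1.25 ± 0.11) rose. Of lysosome genes, 15 rose, 1 fell and 15 were not called (list alone 17 and 1, camera adjusted p = 1.8e-06). CTSD (1.76 ± 0.16) and NEU1 (1.55 ± 0.15) rose. For autophagy, 12 rose, 0 fell and 15 were not called (list alone 12 and 0, camera adjusted p = 0.00150). MAP1LC3B (1.29 ± 0.14) and NBR1 (0.86 ± 0.12) rose. The integrated stress response stayed high: 23 rose, 0 fell and 4 were not called (list alone 25 and 0, camera adjusted p = 3.8e-21). NUPR1 (5.12 ± 0.34) and ATF5 (2.29 ± 0.15) rose.

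**Figure D3:**
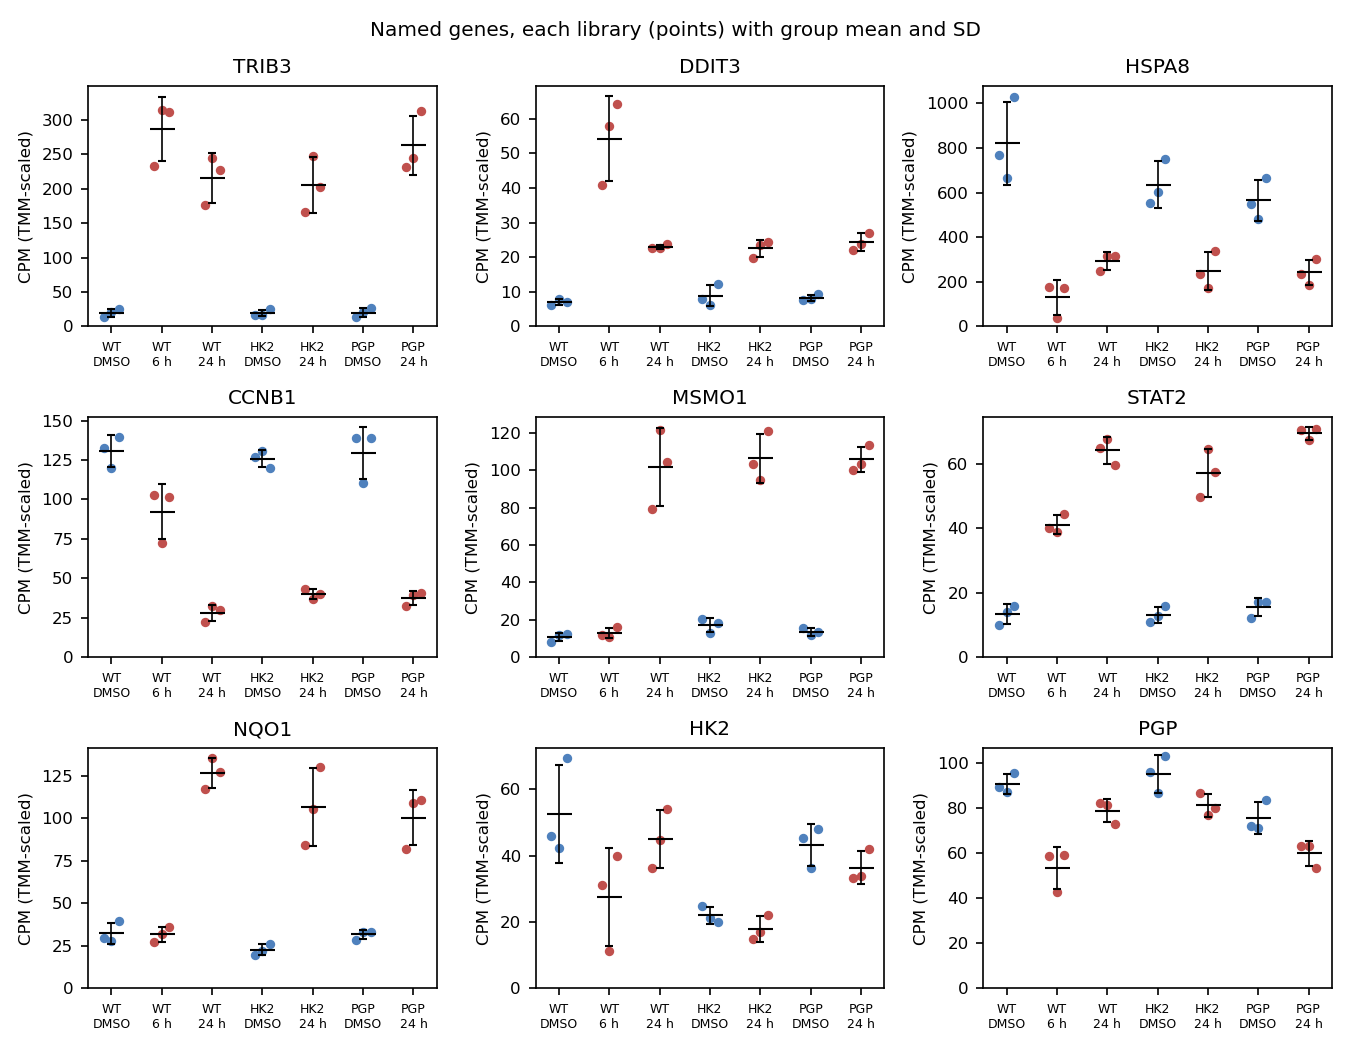
Level of 9 genes in every library (points, CPM scaled by TMM) with the mean and SD of each of the 7 groups (n = 3). TRIB3 rose from 19.5 to 287 CPM at 6 h, and CCNB1 fell from 131 to 28.2 CPM at 24 h in wild type cells.

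A further set of list changes at 24 h was called with the preset correlation and not with an estimated one. For inflammatory and NF-kB targets, 10 rose, 0 fell and 6 were not called (list alone 12 and 0, camera adjusted p = 5.3e-08, adjusted p = 0.0597 with an estimated correlation). TNFAIP3 (1.47 ± 0.19) and CXCL10 (ratio 60.8, 95% interval 20.5 to 298) rose. For HIF targets outside glycolysis, 10 rose, 1 fell and 15 were not called (list alone 10 and 1, camera adjusted p = 0.00103, adjusted p = 0.115 with an estimated correlation). VEGFA (2.68 ± 0.27) and BNIP3L (1.27 ± 0.14) rose. For immediate early genes, 8 rose, 0 fell and 13 were not called (list alone 8 and 0, camera adjusted p = 0.0130, adjusted p = 0.208 with an estimated correlation). DUSP5 (3.30 ± 0.50) and JUND (0.88 ± 0.14) rose. DUSP5 stood at 4.16 without DMSO replicate 1. For cytosolic ribosomal proteins, 10 rose, 0 fell and 67 were not called (list alone 4 and 0, camera adjusted p = 0.0269, adjusted p = 0.406 with an estimated correlation). RPLP1 (0.37 ± 0.08) and RPLP0 (0.38 ± 0.09) rose. The call was lost without 24 h replicate 2 (camera adjusted p = 0.10). For tRNA synthetases, 7 rose, 3 fell and 10 were not called (list alone 9 and 4, camera adjusted p = 0.0289, adjusted p = 0.286 with an estimated correlation). WARS1 (1.58 ± 0.15) and CARS1 (1.20 ± 0.12) rose. The call was lost without DMSO replicate 1 (camera adjusted p = 0.0543) or 24 h replicate 2 (0.0526). Of the 20 lists called at 24 h, 12 held with an estimated correlation: the G2/M, cholesterol, interferon, DNA replication, integrated stress response, MYC, heat shock, mitochondrial ribosome, fatty acid, NRF2, lysosome and autophagy lists.

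At 24 h, the lists of iron handling, heme, dioxygenases, ferroptosis, mitochondrial chaperones, stress relay and calcium, and the tricarboxylic acid cycle were not called as wholes, though single members changed. For iron uptake, storage and export, 3 rose, 0 fell and 9 were not called (list alone 3 and 0, camera adjusted p = 0.187). FTL (1.05 ± 0.10) and ACO1 (0.60 ± 0.16) rose, and the transferrin receptor TFRC stood at 0.22 ± 0.16 (edgeR adjusted p = 0.310). For iron-sulfur cluster assembly and mitochondrial iron, 1 rose, 6 fell and 22 were not called (list alone 1 and 6, camera adjusted p = 0.0696). SLC25A37 (0.66 ± 0.09) rose and CIAPIN1 (-0.81 ± 0.11) fell. For heme synthesis and turnover, 3 rose, 3 fell and 10 were not called (list alone 3 and 3, camera adjusted p = 0.758). BLVRB (0.89 ± 0.14) and ALAS1 (1.18 ± 0.21) rose. For iron- and 2-oxoglutarate-dependent dioxygenases, 4 rose, 0 fell and 25 were not called (list alone 3 and 0, camera adjusted p = 0.246). KDM4B (0.68 ± 0.14) and P4HTM (2.07 ± 0.46) rose. For ferroptosis regulators, 5 rose, 1 fell and 8 were not called (list alone 6 and 2, camera adjusted p = 0.0999). SAT1 (1.43 ± 0.16) and SLC7A11 (1.79 ± 0.36) rose. For mitochondrial chaperones and proteases, 1 rose, 4 fell and 15 were not called (list alone 1 and 2, camera adjusted p = 0.0586). HSPD1 (-0.91 ± 0.10) and HSPE1 (-1.19 ± 0.16) fell. For the mitochondrial stress relay, dynamics and mitophagy, 2 rose, 2 fell and 12 were not called (list alone 2 and 2, camera adjusted p = 0.972). BNIP3L (1.27 ± 0.14) and DELE1 (0.58 ± 0.12) rose. For mitochondrial calcium handling, 2 rose, 4 fell and 9 were not called (list alone 2 and 4, camera adjusted p = 0.351). SLC25A23 (0.93 ± 0.20) rose and VDAC3 (-0.62 ± 0.11) fell. For the tricarboxylic acid cycle and pyruvate entry, 1 rose, 8 fell and 13 were not called (list alone 1 and 9, camera adjusted p = 0.0824). IDH1 (0.77 ± 0.11) rose and IDH2 (-0.57 ± 0.13) fell. With no low-count filter, 4 of these lists were called: iron uptake (median 0.326 against 0.15, camera adjusted p = 0.00982), iron-sulfur clusters (0.00308), mitochondrial chaperones (0.00370) and the tricarboxylic acid cycle (0.00446), none of them with an estimated correlation (adjusted p = 0.462, 0.115, 0.0953 and 0.287). Without 1 library, ferroptosis regulators (DMSO replicate 3, median 0.564 against 0.38, camera adjusted p = 0.0277), mitochondrial chaperones (DMSO replicate 2, 0.0473) and the tricarboxylic acid cycle (24 h replicate 2, 0.0297) were called, and with an estimated correlation ferroptosis regulators had adjusted p = 0.386.

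Among genes of death and metabolism at 24 h, the pro-apoptotic BCL2 family changed in part: 3 rose, 1 fell and 5 were not called (list alone 3 and 2, camera adjusted p = 0.553). BBC3 (0.66 ± 0.14) and PMAIP1 (0.96 ± 0.21) rose. BAX stood at -0.45 ± 0.19 (edgeR adjusted p = 0.0772) and BAK1 at -0.09 ± 0.22 (edgeR adjusted p = 0.795), with BAX past the threshold without DMSO replicate 3 (-0.642, edgeR adjusted p = 0.0190). In the anti-apoptotic BCL2 family, 1 rose, 0 fell and 4 were not called (list alone 1 and 0, camera adjusted p = 0.509). BCL2L2 (1.03 ± 0.36) rose, a call lost without any 1 of 5 libraries (edgeR adjusted p up to 0.134, without DMSO replicate 1), with DESeq2 (0.0842) and with no low-count filter (0.144), while BCL2 stood at 0.23 ± 0.12 and MCL1 at -0.18 ± 0.16. For p53 targets, 4 rose, 6 fell and 18 were not called (list alone 4 and 7, camera adjusted p = 0.345). SESN2 (1.85 ± 0.18) and GDF15 (ratio 41.5, 95% interval 13.9 to 204) rose, and the mean of the list was above 0 where its test was down. For glycolysis and lactate transport, 3 rose, 9 fell and 13 were not called (list alone 5 and 9, camera adjusted p = 0.196). SLC2A3 (1.78 ± 0.15) rose and SLC16A1 (-0.68 ± 0.09) fell. For the pentose phosphate pathway, 3 rose, 1 fell and 5 were not called (list alone 3 and 3, camera adjusted p = 0.408). PGD (1.25 ± 0.11) rose. For metallothioneins and zinc-responsive genes, 0 rose, 3 fell and 6 were not called (list alone 0 and 4, camera adjusted p = 0.0525). MT1E (-0.92 ± 0.16) and MT1X (-0.75 ± 0.16) fell. For the endoplasmic reticulum unfolded protein response, 6 rose, 0 fell and 20 were not called (list alone 5 and 0, camera adjusted p = 0.0568). XBP1 (0.82 ± 0.14) and SEL1L (0.49 ± 0.10) rose. With no low-count filter, the glycolysis (camera adjusted p = 0.0254), metallothionein (0.00370) and endoplasmic reticulum (0.00445) lists were called, the last also in a fit of both groups alone (0.0296), and leaving out 1 library gave down to 0.0201 for metallothioneins and 0.0374 for the endoplasmic reticulum list. None passed with an estimated correlation (adjusted p = 0.406, 0.322 and 0.322).

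**Figure D4:**
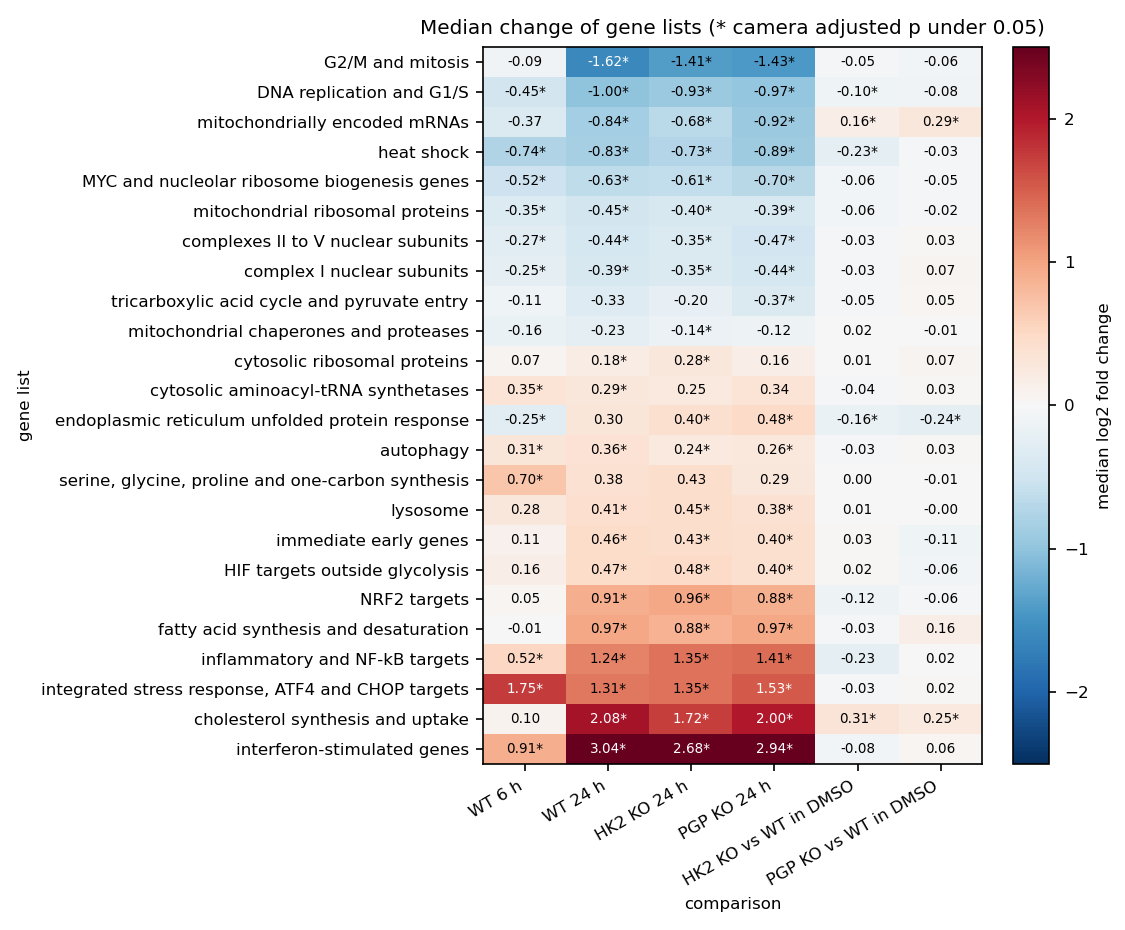
Median log2 fold change of each gene list called in at least 1 comparison of ironomycin with DMSO (rows), in 6 comparisons (columns). A star marks a camera adjusted p under 0.05 with the preset correlation. The G2/M list moved from −0.09 at 6 h to −1.62 at 24 h in wild type cells.

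Between 6 h and 24 h in wild type cells, mitotic genes fell and sterol genes rose. TPX2, a spindle assembly factor, went from 196 ± 36.9 to 51.9 ± 8.30 CPM (-1.91 ± 0.14), and HMGCS1, an early enzyme of cholesterol synthesis, from 4.16 ± 0.829 to 46.1 ± 9.30 CPM (3.46 ± 0.26). DDIT3 fell from 54.3 ± 12.2 to 23.0 ± 0.642 CPM (-1.24 ± 0.18). In all, 1922 genes were called, 984 higher and 938 lower at 24 h (edgeR). The count was 1271 without 24 h replicate 3, 1600 without 6 h replicate 2 and 749 in a fit of both groups alone. Of G2/M genes, 0 of 34 members rose, 34 fell and 0 were not called (list alone 0 and 34, camera adjusted p = 2.2e-92). CCNB2 (-1.56 ± 0.12) fell. For cholesterol synthesis and uptake, 22 rose, 0 fell and 1 was not called (list alone 22 and 0, camera adjusted p = 6.8e-53). MSMO1 (2.96 ± 0.19) rose. For fatty acid synthesis, 10 rose, 0 fell and 3 were not called (list alone 10 and 0, camera adjusted p = 1.8e-14). PNPLA3 (2.67 ± 0.23) rose, and replicate 2 deviated by -0.28. For NRF2 targets, 13 rose, 0 fell and 9 were not called (list alone 14 and 0, camera adjusted p = 1.6e-13). NQO1 (1.99 ± 0.17) rose, and replicate 2 deviated by 0.26. For the endoplasmic reticulum response, 13 rose, 0 fell and 13 were not called (list alone 13 and 0, camera adjusted p = 5.9e-08). CRELD2 (1.41 ± 0.15) rose, and replicate 2 deviated by -0.20. For lysosome genes, 10 rose, 1 fell and 20 were not called (list alone 13 and 1, camera adjusted p = 9.3e-05). CTSD (1.10 ± 0.15) rose. These 6 of the 18 lists called held with an estimated correlation. The largest rises among genes of at least 5 CPM were IFI44L, with a ratio of 393 (95% interval 70.1 to 15550), EPSTI1 (176, 31.1 to 6972), IFI27 (111, 37.5 to 539), SIGLEC1 (79.05, 21.5 to 658) and OAS1 (4.31 ± 0.56), and without 24 h replicate 1 the ratios were 242, 119, 60.2 and 33.0. The largest falls were IGLL1 (-3.49 ± 0.37), PIF1 (-2.66 ± 0.20), PLK1 (-2.23 ± 0.19), MT-TL1 (-2.18 ± 0.22) and MT-TC (-2.18 ± 0.27).

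The other 12 lists called between 6 h and 24 h lost the call with an estimated correlation. For interferon-stimulated genes, 23 rose, 0 fell and 5 were not called (list alone 27 and 0, camera adjusted p = 6.4e-20, adjusted p = 0.0727 with an estimated correlation). IFI6 (3.70 ± 0.42) rose. For mitochondrially encoded mRNAs, 0 rose, 9 fell and 4 were not called (list alone 0 and 11, camera adjusted p = 3.5e-10, adjusted p = 0.159 with an estimated correlation). MT-ND6 (-1.22 ± 0.14) fell, and replicate 2 deviated by 0.39. For DNA replication and G1/S, 2 rose, 20 fell and 21 were not called (list alone 2 and 26, camera adjusted p = 6.6e-10, adjusted p = 0.187 with an estimated correlation). MCM7 (-1.13 ± 0.11) fell. For iron uptake, storage and export, 4 rose, 0 fell and 8 were not called (list alone 6 and 1, camera adjusted p = 0.00378, adjusted p = 0.193 with an estimated correlation). FTL (0.78 ± 0.10) rose, and replicate 2 deviated by -0.42. For serine, glycine and one-carbon synthesis, 2 rose, 10 fell and 8 were not called (list alone 3 and 10, camera adjusted p = 0.00398, adjusted p = 0.193 with an estimated correlation). MTHFD1 (-0.53 ± 0.10) fell. For complexes II to V, 0 rose, 11 fell and 28 were not called (list alone 0 and 15, camera adjusted p = 0.00398, adjusted p = 0.450 with an estimated correlation). CYC1 (-0.46 ± 0.09) fell. For complex I, 0 rose, 6 fell and 30 were not called (list alone 0 and 8, camera adjusted p = 0.0318, adjusted p = 0.429 with an estimated correlation). NDUFV1 (-0.88 ± 0.13) fell. For HIF targets, 8 rose, 0 fell and 18 were not called (list alone 9 and 0, camera adjusted p = 0.00398, adjusted p = 0.193 with an estimated correlation). NDRG1 (1.37 ± 0.17) rose, and replicate 2 deviated by -0.41. For the integrated stress response, 1 rose, 6 fell and 20 were not called (list alone 1 and 7, camera adjusted p = 0.00572, adjusted p = 0.384 with an estimated correlation). DDIT3 (-1.24 ± 0.18) fell.

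For tRNA synthetases between 6 h and 24 h, 0 rose, 6 fell and 14 were not called (list alone 0 and 9, camera adjusted p = 0.0153, adjusted p = 0.289 with an estimated correlation). VARS1 (-0.92 ± 0.16) fell. For metallothioneins, 0 rose, 3 fell and 6 were not called (list alone 0 and 4, camera adjusted p = 0.0271, adjusted p = 0.347 with an estimated correlation). MT1E (-0.84 ± 0.16) fell. For inflammatory and NF-kB targets, 3 rose, 0 fell and 13 were not called (list alone 3 and 0, camera adjusted p = 0.0271, adjusted p = 0.450 with an estimated correlation). TNFAIP2 (1.14 ± 0.20) rose. The complex I list lost its call without 24 h replicate 1 (camera adjusted p = 0.140) and in a fit of both groups alone (0.0614). The tRNA synthetase list lost it without 6 h replicate 2 (camera adjusted p = 0.0592), and the NF-kB list without 6 h replicate 1 (0.295). Metallothioneins lost it without 6 h replicate 3 (camera adjusted p = 0.161) or 24 h replicate 3 (0.0547).

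In the HK2 knockout, mitotic genes fell and sterol, stress and interferon genes rose at 24 h of ironomycin. CCNB1 fell from 126 ± 5.27 to 40.2 ± 3.20 CPM (-1.65 ± 0.15), while MSMO1 rose by 2.62 ± 0.19 and TRIB3 by 3.42 ± 0.24. In all, 3418 genes were called, 1847 higher and 1571 lower (edgeR). Of G2/M genes, 0 of 34 members rose, 34 fell and 0 were not called (list alone 0 and 34, camera adjusted p = 2.5e-50). For cholesterol synthesis and uptake, 19 rose, 0 fell and 4 were not called (list alone 22 and 0, camera adjusted p = 3.8e-27). For DNA replication and G1/S, 0 rose, 38 fell and 5 were not called (list alone 0 and 41, camera adjusted p = 3.2e-23). RRM1 (-1.12 ± 0.12) fell. For the integrated stress response, 24 rose, 0 fell and 3 were not called (list alone 24 and 0, camera adjusted p = 1.7e-21). ATF5 (2.30 ± 0.15) rose. For interferon-stimulated genes, 25 rose, 0 fell and 3 were not called (list alone 26 and 0, camera adjusted p = 7.1e-18). STAT2 (2.11 ± 0.16) rose. For MYC and nucleolar genes, 0 rose, 25 fell and 8 were not called (list alone 0 and 27, camera adjusted p = 2.7e-13). UTP20 (-1.32 ± 0.12) fell. For NRF2 targets, 14 rose, 0 fell and 8 were not called (list alone 17 and 0, camera adjusted p = 4.6e-09). NQO1 (2.23 ± 0.17) rose. For inflammatory and NF-kB targets, 13 rose, 0 fell and 3 were not called (list alone 13 and 0, camera adjusted p = 5.1e-09). NFKBIA (1.05 ± 0.13) rose. KLHDC7B, with 0 counts in DMSO, was at least 57.6-fold higher. CXCL10 and IFI44L, each with 3 counts in DMSO, had ratios of 67.5 (95% interval 22.7 to 330.1) and 51.8 (17.4 to 254). The other largest rises among genes of at least 5 CPM were ORM1 (5.42 ± 0.58, and 6.61 without DMSO replicate 2) and IFI27 (4.86 ± 0.86). The largest falls were S100A8 (-3.15 ± 0.35), IGLL1 (-2.69 ± 0.33), MNDA (-2.45 ± 0.32), MS4A4A (-2.42 ± 0.36) and ACP3 (-2.34 ± 0.30).

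Further lists moved in the HK2 knockout at 24 h. For heat shock genes, 1 rose, 15 fell and 6 were not called (list alone 1 and 15, camera adjusted p = 9.1e-09). HSPH1 (-1.47 ± 0.12) fell. Of mitochondrial ribosomal proteins, 0 rose, 31 fell and 40 were not called (list alone 0 and 35, camera adjusted p = 1.9e-08). MRPS7 (-0.99 ± 0.14) fell. In fatty acid synthesis, 11 rose, 0 fell and 2 were not called (list alone 11 and 0, camera adjusted p = 1.3e-07). PNPLA3 (1.92 ± 0.21) rose. Of lysosome genes, 17 rose, 0 fell and 14 were not called (list alone 18 and 0, camera adjusted p = 8.3e-07). Of autophagy genes, 10 rose, 0 fell and 17 were not called (list alone 10 and 0, camera adjusted p = 0.00856). These 5 lists and those of G2/M, cholesterol, DNA replication, the integrated stress response, interferon, MYC, NRF2 and NF-kB made up the 13 of 21 called lists that held with an estimated correlation. For cytosolic ribosomal proteins, 36 rose, 0 fell and 41 were not called (list alone 44 and 0, camera adjusted p = 1.2e-05, adjusted p = 0.151 with an estimated correlation). RPL3 (0.48 ± 0.08) rose. For complexes II to V, 0 rose, 20 fell and 19 were not called (list alone 0 and 26, camera adjusted p = 3.2e-07, adjusted p = 0.151 with an estimated correlation). For complex I, 0 rose, 14 fell and 22 were not called (list alone 0 and 18, camera adjusted p = 7.8e-06, adjusted p = 0.0721 with an estimated correlation). For mitochondrially encoded mRNAs, 2 rose, 8 fell and 3 were not called (list alone 2 and 8, camera adjusted p = 1.6e-04, adjusted p = 0.295 with an estimated correlation). MT-ATP6 (-1.78 ± 0.21) fell. For HIF targets, 10 rose, 1 fell and 15 were not called (list alone 10 and 2, camera adjusted p = 0.00381, adjusted p = 0.151 with an estimated correlation). VEGFA (2.48 ± 0.27) rose. For the endoplasmic reticulum response, 9 rose, 0 fell and 17 were not called (list alone 9 and 0, camera adjusted p = 0.00580, adjusted p = 0.151 with an estimated correlation). For immediate early genes, 7 rose, 1 fell and 13 were not called (list alone 8 and 1, camera adjusted p = 0.00856, adjusted p = 0.193 with an estimated correlation). For mitochondrial chaperones and proteases, 1 rose, 6 fell and 13 were not called (list alone 1 and 6, camera adjusted p = 0.0440, adjusted p = 0.0721 with an estimated correlation). HSPD1 (-0.93 ± 0.10) fell. That call was lost without DMSO replicate 2 (camera adjusted p = 0.0524), 24 h replicate 1 (0.0563) or 24 h replicate 2 (0.0695), and in a fit of both groups alone (0.0800).

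In the PGP knockout, mitotic genes fell and sterol and stress genes rose at 24 h too. AURKA, a mitotic kinase, fell from 210.2 ± 28.1 to 57.4 ± 1.92 CPM (-1.87 ± 0.16), MSMO1 rose by 2.97 ± 0.19 and TRIB3 by 3.70 ± 0.24. In all, 3661 genes were called, 1869 higher and 1792 lower (edgeR), and 4081 with the replicate number as a block. Of G2/M genes, 0 of 34 members rose, 34 fell and 0 were not called (list alone 0 and 34, camera adjusted p = 6.0e-50). For cholesterol synthesis and uptake, 20 rose, 1 fell and 2 were not called (list alone 21 and 1, camera adjusted p = 4.4e-26). For DNA replication and G1/S, 0 rose, 35 fell and 8 were not called (list alone 0 and 36, camera adjusted p = 3.1e-21). MCM7 (-1.28 ± 0.11) fell. For the integrated stress response, 22 rose, 0 fell and 5 were not called (list alone 24 and 0, camera adjusted p = 1.8e-20). ATF5 (2.32 ± 0.15) rose. For interferon-stimulated genes, 26 rose, 0 fell and 2 were not called (list alone 26 and 0, camera adjusted p = 2.3e-20). XAF1 (2.83 ± 0.19) rose. For MYC and nucleolar genes, 0 rose, 27 fell and 6 were not called (list alone 0 and 29, camera adjusted p = 6.3e-14). PA2G4 (-0.91 ± 0.08) fell. For NRF2 targets, 13 rose, 1 fell and 8 were not called (list alone 14 and 2, camera adjusted p = 6.8e-07). PGD (1.16 ± 0.11) rose. For complex I, 0 rose, 23 fell and 13 were not called (list alone 0 and 27, camera adjusted p = 1.3e-07). NDUFS5 (-1.13 ± 0.11) fell. KLHDC7B and EPSTI1, with 0 counts in DMSO, were at least 102-fold and at least 53.7-fold higher. IFI44L, with 1 count, had a ratio of 263.5 (95% interval 46.9 to 10440), and CXCL10, with 3 counts, of 68.3 (23.1 to 334). Without 24 h replicate 1 the EPSTI1 floor gave 22.5 and the IFI44L ratio was 88.2, and without DMSO replicate 3 the fitted log2 value of CXCL10 was 9.26, and without replicate 2 it was 5.36. The other of the 5 largest rises among genes of at least 5 CPM was ORM1 (5.60 ± 0.54), and the largest falls, apart from the pseudogene MTCO2P12, were IGLL1 (-3.35 ± 0.34), S100A8 (-2.95 ± 0.34), FAM83D (-2.41 ± 0.21) and MS4A4A (-2.37 ± 0.37).

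Further lists moved in the PGP knockout at 24 h. For heat shock genes, 0 rose, 16 fell and 6 were not called (list alone 1 and 16, camera adjusted p = 6.6e-11). HSP90AA1 (-1.19 ± 0.10) fell. Of mitochondrial ribosomal proteins, 0 rose, 37 fell and 34 were not called (list alone 0 and 37, camera adjusted p = 3.0e-09). MRPL44 (-1.02 ± 0.14) fell. In fatty acid synthesis, 11 rose, 0 fell and 2 were not called (list alone 11 and 0, camera adjusted p = 1.4e-08). PNPLA3 (2.90 ± 0.24) rose. Of lysosome genes, 13 rose, 2 fell and 16 were not called (list alone 17 and 2, camera adjusted p = 2.6e-04). Of autophagy genes, 10 rose, 0 fell and 17 were not called (list alone 10 and 0, camera adjusted p = 0.00515). These 5 lists and those of G2/M, cholesterol, DNA replication, the integrated stress response, interferon, MYC, NRF2 and complex I made up the 13 of 20 called lists that held with an estimated correlation. For complexes II to V, 0 rose, 29 fell and 10 were not called (list alone 0 and 32, camera adjusted p = 2.0e-11, adjusted p = 0.0584 with an estimated correlation). COX7B (-0.90 ± 0.12) fell. For inflammatory and NF-kB targets, 12 rose, 0 fell and 4 were not called (list alone 13 and 0, camera adjusted p = 3.4e-07, adjusted p = 0.0734 with an estimated correlation). CXCL10 (ratio 68.3, 95% interval 23.1 to 334) rose. For mitochondrially encoded mRNAs, 1 rose, 9 fell and 3 were not called (list alone 1 and 10, camera adjusted p = 6.1e-06, adjusted p = 0.191 with an estimated correlation). MT-ATP6 (-2.20 ± 0.21) fell. For HIF targets, 11 rose, 1 fell and 14 were not called (list alone 11 and 1, camera adjusted p = 6.9e-04, adjusted p = 0.113 with an estimated correlation). VEGFA (2.91 ± 0.28) rose. For the endoplasmic reticulum response, 10 rose, 0 fell and 16 were not called (list alone 11 and 0, camera adjusted p = 0.00641, adjusted p = 0.176 with an estimated correlation). XBP1 (0.86 ± 0.14) rose. For immediate early genes, 6 rose, 0 fell and 15 were not called (list alone 6 and 0, camera adjusted p = 0.00860, adjusted p = 0.191 with an estimated correlation). KLF6 (1.43 ± 0.23) rose. For the tricarboxylic acid cycle, 1 rose, 7 fell and 14 were not called (list alone 1 and 7, camera adjusted p = 0.0335, adjusted p = 0.187 with an estimated correlation). IDH1 (0.79 ± 0.11) rose. For tRNA synthetases, 11 rose, 4 fell and 5 were not called (list alone 11 and 4, camera adjusted p = 0.0571). WARS1 (1.59 ± 0.15) rose. For cytosolic ribosomal proteins, 8 rose, 1 fell and 68 were not called (list alone 0 and 0, camera adjusted p = 0.0592). RPS27 (0.48 ± 0.12) rose. For ferroptosis regulators, 5 rose, 2 fell and 7 were not called (list alone 6 and 2, camera adjusted p = 0.125). SAT1 (1.28 ± 0.16) rose. With the replicate number as a block these 3 were called (camera adjusted p = 0.0375, 0.0397 and 0.0375), and with an estimated correlation none was (adjusted p = 0.325, 0.474 and 0.390).

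In DMSO, 1 gene was called between the HK2 knockout and wild type. OFD1, a centriole protein, was that gene: it rose from 55.0 ± 10.7 CPM in wild type to 97.7 ± 2.64 in the knockout (0.83 ± 0.13, edgeR adjusted p = 0.0353). The call was lost without wild type DMSO replicate 1 (edgeR adjusted p = 0.0948) or 3 (0.306), or without knockout replicate 1 (0.147), 2 (0.247) or 3 (0.0825). Without wild type DMSO replicate 2 the count was 8, and without 6 h replicate 2 it was 11. At an unadjusted p under 0.05, 606 genes passed, where chance gives 580.5. DESeq2 called 23, a fit of the compared groups alone 17, the GC and length offset 5 and the fit with no low-count filter 59. In simulated data for this comparison, edgeR recovered 37 of 50 genes changed 2-fold.

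In 7 lists, camera found a direction between the HK2 knockout and wild type in DMSO, and 0 of the 7 held with an estimated correlation. Cholesterol synthesis and uptake lay higher: 0 rose, 0 fell and 23 were not called (list alone 4 and 0, camera adjusted p = 1.5e-08, adjusted p = 0.166 with an estimated correlation). Heat shock genes lay lower: 0 rose, 0 fell and 22 were not called (list alone 0 and 4, camera adjusted p = 3.1e-06, adjusted p = 0.0810 with an estimated correlation). HSP90AA1 stood at -0.28 ± 0.10. For mitochondrially encoded mRNAs, higher, 0 of 13 members were called, also over the list alone (camera adjusted p = 0.00595, adjusted p = 0.708 with an estimated correlation). MT-CO3 stood at 0.11 ± 0.21. For p53 targets, lower, 0 of 28 members were called, also over the list alone (camera adjusted p = 0.00595, adjusted p = 0.0810 with an estimated correlation). CDKN1A stood at -0.36 ± 0.15. For DNA replication, lower, 0 of 43 members were called, also over the list alone (camera adjusted p = 0.00595, adjusted p = 0.708 with an estimated correlation), and for the endoplasmic reticulum response, lower, 0 of 26 members were called, also over the list alone (camera adjusted p = 0.0156, adjusted p = 0.638 with an estimated correlation). HSPA5 stood at -0.47 ± 0.17. HSPA5 was past the threshold with no low-count filter (edgeR adjusted p = 0.0458), and MT-CO3 lay between -0.0352 and 0.304 on leaving out 1 library. For B-lymphoid markers, lower, 0 rose, 0 fell and 6 were not called (list alone 0 and 1, camera adjusted p = 0.0156, adjusted p = 0.439 with an estimated correlation). Leaving out single libraries ended 5 of the 7 calls, at camera adjusted p-values of up to 0.338 for the endoplasmic reticulum list (without knockout replicate 1), 0.136 for mitochondrial mRNAs (wild type replicate 2), 0.112 for p53 targets (wild type replicate 1), 0.0638 for DNA replication (knockout replicate 1) and 0.331 for B-lymphoid markers (wild type replicate 2). The call of B-lymphoid markers also ended with no low-count filter (camera adjusted p = 0.174) and in a fit of the compared groups alone (0.606), where their median went from -0.61 to -0.00340.

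Between the PGP knockout and wild type in DMSO, edgeR called 0 of 11610 genes, 648 passed an unadjusted p under 0.05 where chance gives 580.5, and DESeq2 called 5, a fit of the compared groups alone 2 and the fit with no low-count filter 96. In simulated data for this comparison, edgeR recovered 24 of 50 genes changed 2-fold and 46 of 50 changed 4-fold. Of 4 lists with a direction, 0 held with an estimated correlation. Cholesterol synthesis and uptake lay higher: 0 of 23 members were called, also over the list alone (camera adjusted p = 7.0e-06, adjusted p = 0.542 with an estimated correlation). Mitochondrially encoded mRNAs also lay higher: 0 of 13 members were called, also over the list alone (camera adjusted p = 7.7e-05, adjusted p = 0.684 with an estimated correlation). MT-CO3 stood at 0.40 ± 0.21. For the endoplasmic reticulum response, lower, 0 of 26 members were called, also over the list alone (camera adjusted p = 0.0156, adjusted p = 0.542 with an estimated correlation). HSPA5 stood at -0.05 ± 0.17. For granule proteins of immature myeloid cells, higher, 0 of 11 members were called, also over the list alone (camera adjusted p = 0.0345, adjusted p = 0.542 with an estimated correlation). HSPA5 lay between -0.171 and 0.102 on leaving out 1 library. The calls of the last 2 lists were lost without wild type DMSO replicate 3 (camera adjusted p = 0.0553 and 0.255) or PGP knockout replicate 3 (0.0804 and 0.0896), and that of the granule proteins without PGP knockout replicate 2 (0.0605).

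Whether a knockout changed the response to ironomycin was tested as the difference between its 24 h fold change and that of wild type. edgeR called 0 genes for HK2 (267 at an unadjusted p under 0.05) and 0 for PGP (221), and DESeq2 called 0 and 0 (208 and 150 unadjusted). For edgeR chance gives 580.5, so the test may be too strict, and 0 calls do not show equal responses. With no low-count filter the counts were 17 and 18, and in a fit of the compared groups alone PGP gave 1. In simulated data edgeR recovered 21 of 50 genes with a 2-fold difference for HK2 and 22 of 50 for PGP, and 39 and 41 of 50 with a 4-fold difference. G2/M genes moved less in the HK2 knockout, with a median difference of 0.27: 0 of 34 members were called, also over the list alone (camera adjusted p = 1.7e-09, adjusted p = 0.359 with an estimated correlation). TOP2A stood at 0.25 ± 0.20. Interferon-stimulated genes rose less, by a median of -0.58: 0 of 28 members were called, also over the list alone (camera adjusted p = 1.0e-06, adjusted p = 0.651 with an estimated correlation). XAF1 stood at -0.58 ± 0.25. For cholesterol synthesis and uptake, the median was -0.27: 0 of 23 members were called, also over the list alone (camera adjusted p = 9.0e-06, adjusted p = 0.528 with an estimated correlation). In the PGP knockout the medians were 0.20 for G2/M genes (camera adjusted p = 7.9e-05) and -0.20 for cholesterol genes (0.00234), each with adjusted p = 0.699 with an estimated correlation. There 0 of 34 and 0 of 23 members were called, also over the list alone. The cholesterol call was lost in HK2 without knockout DMSO replicate 1 (camera adjusted p = 0.0573), and in PGP without wild type 24 h replicate 2 (0.277) or knockout DMSO replicate 1 (0.225).

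The 24 h responses of the 3 genotypes ran closely in parallel across genes. Over 11610 genes, which are not independent replicates, the fold changes of wild type and the HK2 knockout correlated at r = 0.833 (covariance 0.446), and those of wild type and the PGP knockout at r = 0.836 (covariance 0.471), with no shared library. With the HK2 knockout, 1338 genes were higher and 1235 lower in both, where independent lists would share 282 and 229, and 0 genes went opposite ways. With the PGP knockout, 1358 were higher and 1379 lower in both, where independent lists would share 286 and 261, and 2 went opposite ways. Without the low-count filter r was 0.264 and 0.276. The 6 h and 24 h responses of wild type, which share the DMSO libraries, correlated at r = 0.644 (covariance 0.299), against 0.492 (covariance 0.0503) in 20 simulations of unchanged groups. Of genes called at both times, 762 were higher and 728 lower, where independent lists would share 194 and 187, and 24 went opposite ways. In DMSO the HK2 and PGP knockouts' differences from wild type correlated at r = 0.430 (covariance 0.0528), against 0.487 (covariance 0.0507) in simulation.

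**Figure D5:**
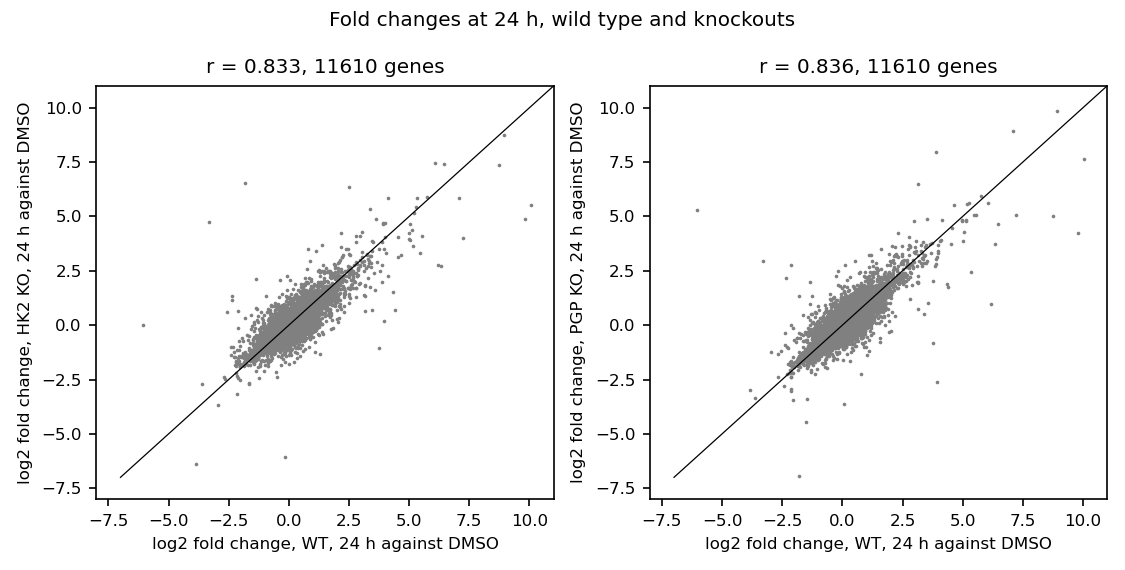
Log2 fold change at 24 h of ironomycin against DMSO in wild type cells (x axis) and in the HK2 or PGP knockout (y axis), each point 1 of 11610 genes, with the line of equal change. The correlations were 0.833 and 0.836.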

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

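Of the tests in this part, the count of list calls that hold with an estimated correlation and the split by medians nearer 0 or farther from it were chosen after the result was seen, and the response scores and the other splits of the libraries were set before. The median difference in response was 0.27 (HK2) and 0.203 (PGP) for G2/M genes (adjusted p = 0.359 and 0.699 with an estimated correlation). For cholesterol genes it was -0.267 and -0.204 (0.528 and 0.699), and 0 members of either list were called. Interferon-stimulated genes, also with 0 called, differed by -0.576 in the HK2 knockout (0.651). There, B-lymphoid markers differed by 0.653, fatty acid synthesis by -0.114, complexes II to V by 0.119 and cytosolic ribosomal proteins by 0.125. For fatty acid synthesis, 0 rose, 0 fell and 13 were not called (0 and 1 adjusted over the list alone, camera adjusted p = 0.0289, adjusted p = 0.644 with an estimated correlation). Of complexes II to V, cytosolic ribosomal proteins and B-lymphoid markers, 0 of 39, 0 of 77 and 0 of 6 members were called, also over the list alone. Their camera adjusted p-values were 0.00825, 8.1e-05 and 0.0348, and with an estimated correlation 0.788, 0.644 and 0.623. Between 6 h and 24 h, 18 lists were called.

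Fatty acid synthesis lost its call at a camera adjusted p of 0.226 without HK2 knockout 24 h replicate 2, complexes II to V at 0.166 without wild type 24 h replicate 1, and B-lymphoid markers at 0.144 without wild type DMSO replicate 2.

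In 7 of the 9 list calls the median was nearer 0 at 24 h in the knockout than in wild type, and 2 explanations were weighed. In the other 2, it was farther from 0 in the HK2 knockout, for cytosolic ribosomal proteins (0.278 against 0.183) and B-lymphoid markers (1.37 against 0.714), which a smaller overall response does not predict. Genes of a list that move together in the residuals could give all these calls, and 0 of the 9 held with an estimated correlation. A smaller response would lower the response score, the mean fold change along the genes called in the other knockout. It differed from wild type by -0.0603 (SE 0.0399, -0.0809 to -0.0301 on leaving out 1 library) for HK2, with an exact permutation p of 0.165 over 400 arrangements, and by -0.0108 (SE 0.0314, -0.0303 to 0.0063) for PGP, with an exact permutation p of 0.76, so neither a smaller response behind the 7 calls nor an equal one can be ruled out.

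Other splits of the same libraries were counted for each gene count. With 10 splits per comparison of 2 groups, the share cannot fall under 0.1, so these splits decide nothing. The real split gave 2556 genes at 6 h, 3465 at 24 h, 1922 between the times, 3418 and 3661 in the HK2 and PGP knockouts at 24 h and 1 in the HK2 knockout in DMSO, each reached by 1 of 10 splits, with 0 as the highest of the others. In the PGP knockout in DMSO the real split gave 0, as did all 10. For the differences in response the real splits gave 0 genes, reached by 60 of 60 splits each, with 52 (HK2) and 21 (PGP) as the highest of the others.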

How the results depend on the processing

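The GC and length offset was chosen after the result was seen. Leaving 6 h replicate 2 out of comparisons that do not include it was also unplanned, and the other settings were planned. In a fit of the compared groups alone, 1212 genes were called at 6 h, 749 between the times, 17 (HK2) and 2 (PGP) in DMSO, and 1 for the PGP difference in response. With no low-count filter there were 59 and 96 in DMSO and 17 and 18 for the differences in response. DESeq2 called 23 and 5 in DMSO, and the offset 5 for HK2. With the replicate number as a block (replicate block) 19 genes were called in the HK2 knockout in DMSO, HK2 among them (0.0237), MT-RNR2 gained a call at 6 h; list tests gained 13 calls and lost 0, and no other count moved by over 1.5 times. Of these, 3 were in the PGP knockout at 24 h, taken as paired, and the block changed no other call of a list or named gene there. In wild type at 24 h they were ferroptosis regulators (0.0241), mitochondrial chaperones (0.0475), the endoplasmic reticulum list (0.0304) and epithelial and fibroblast markers (0.0478), with adjusted p = 0.386, 0.0953, 0.322 and 0.123 with an estimated correlation. In each of the other 8 comparisons at least 1 pair of same-numbered libraries correlated at 0.1 or less, so whether the numbers mark anything shared stays open: over all groups the mean was 0.116 (-0.0864 to 0.347), 31 of 63 pairs were over 0.1, and 19 of 21 libraries correlated best with their own number, a hint from the data and not the design. The check was made on all pairs together at first, and for each comparison after the calls of both fits had been seen. With no low-count filter list tests gained 38 calls and lost 1, and in the compared groups alone they gained 8 and lost 3. Besides those of wild type at 24 h, the calls gained with no filter were, in the PGP knockout at 24 h, iron-sulfur clusters (0.00612), dioxygenases (0.0199, and 0.0366 in the compared groups alone), tRNA synthetases (0.0262), glycolysis (0.00754), cytosolic ribosomal proteins (6.9e-04), metallothioneins (0.00704), T- and NK-cell markers (0.0191) and nuclear RNAs (0.0199); in the HK2 knockout at 24 h, iron uptake (0.0416), iron-sulfur clusters (0.00355), tRNA synthetases (0.0487), glycolysis (0.0497) and nuclear RNAs (0.0437); at 6 h, iron-sulfur clusters (0.00759), mitochondrial chaperones (0.0197), calcium handling (0.00386), glycolysis (0.00499), the tricarboxylic acid cycle (0.0367) and lysosome (0.0312); and 10 in other comparisons. With an estimated correlation none of these lists passed, the lowest adjusted p being 0.0734 (dioxygenases). Mitochondrially encoded mRNAs in the HK2 difference in response, with a median of 0.27 and a camera adjusted p of 0.0519, were called with the replicate block (0.00714), with no filter (0.0432) and without any 1 of 7 libraries (down to 0.00368), while the estimated correlation gave 0.820. Interferon-stimulated genes in the PGP one, with a median of -0.20 and a camera adjusted p of 0.0853, were called with the replicate block (0.0348) and without any 1 of 4 libraries (down to 9.9e-12), while the estimated correlation gave 0.985. With an estimated correlation, 51 of 112 list calls held. RLE size factors changed no call of a list.

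The correlation of the 24 h responses of wild type and the HK2 knockout was 0.264 with no filter and 0.881 in the compared groups alone, for the PGP knockout 0.276 and 0.886, and for 6 h and 24 h 0.51 with no filter. Leaving out 1 library gave 0.79 to 0.815 for HK2, 0.795 to 0.821 for PGP, 0.569 to 0.69 for 6 h and 24 h and 0.333 to 0.562 for the knockouts in DMSO. Gene counts ranged from 1776 to 2594 at 6 h, 2787 to 3984 at 24 h, 1271 to 2220 between the times, 2663 to 3930 and 2874 to 4187 in the HK2 and PGP knockouts at 24 h, and 0 to 11 in the HK2 knockout in DMSO. Signs changed for DNA replication in the HK2 difference in response (-0.0276 to 0.224) and the PGP one (-0.0530 to 0.188), complexes II to V in the PGP one (-0.125 to 0.0225), TFRC (-0.0787 to 0.198) and BAX (-0.305 to 0.0193) at 6 h, MT-CO3 in the HK2 knockout (-0.0352 to 0.304) and HSPA5 in the PGP knockout in DMSO (-0.171 to 0.102). With 1 library left out, 48 list tests were weaker and 69 stronger.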

Other observations

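Of the tests in this part, those of depth, of mixing, of a priming rise shared by all small RNAs and of distance from the promoter were chosen after the result was seen, and those of GC content and of the small RNA median before it. Lists of lineage markers were not called as bodies at 24 h in wild type cells. For monocyte and macrophage markers, 3 rose, 3 fell and 13 were not called (3 and 3 adjusted over the list alone, camera adjusted p = 0.946). CEBPB (1.62 ± 0.24) rose and S100A8 (-2.14 ± 0.33) fell. For granule proteins, 3 rose, 5 fell and 3 were not called (list alone 4 and 5, camera adjusted p = 0.777). CST7 (2.54 ± 0.27) and CTSG (0.81 ± 0.12) rose. For B-lymphoid markers, 2 rose, 1 fell and 3 were not called (list alone 2 and 1, camera adjusted p = 0.777). PAX5 (1.99 ± 0.44) rose and IGLL1 (-3.61 ± 0.37) fell. For T- and NK-cell markers, 2 rose, 0 fell and 1 was not called (list alone 2 and 0, camera adjusted p = 0.0525). NKG7 (1.53 ± 0.19) rose. For epithelial and fibroblast markers, 2 rose, 0 fell and 1 was not called (list alone 2 and 0, camera adjusted p = 0.0689). COL6A1 (ratio 93.3, 95% interval 16.3 to 3726) rose, and its fitted log2 value was 7.84 without DMSO replicate 3. For the KMT2A-rearranged leukaemia programme, 1 rose, 1 fell and 13 were not called (list alone 0 and 1, camera adjusted p = 0.777). SOX4 (-0.77 ± 0.11) fell. For nuclear-retained long RNAs, 5 rose, 1 fell and 4 were not called (list alone 6 and 1, camera adjusted p = 0.0856). NEAT1 (1.16 ± 0.18) rose and SNHG12 (-1.03 ± 0.12) fell. With no low-count filter, the T- and NK-cell list (camera adjusted p = 0.00787) and the nuclear RNA list (0.0118) were called, and in a fit of both groups alone the epithelial and fibroblast list (0.0424). None of the 3 passed with an estimated correlation (adjusted p = 0.114, 0.322 and 0.123). Leaving out 1 library gave down to 0.0255 for T- and NK-cell and 0.0473 for epithelial markers. Of erythroid markers, 2 members were measured, too few for camera, and 0 were called.

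Replicate 2 of wild type at 6 h lay apart, with 1011 genes lower by over 1 log2 and 226 higher than in the other 2 libraries. GC content of the transcript ends and transcript length accounted for 8.88% of the variance of its deviation (SE 0.512 over 500 draws), which argues against them as the whole cause. The correlation of its deviation with GC content (rho 0.36) was the highest of the 21 libraries, so a part may be technical. Its depth of 4754779 lay above the lowest of the others, 3829274. Mixing with DMSO or 24 h cells accounted for 1.36% of the variance over the genes called without it, which argues against a wrong label.

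Mitochondrial transcripts moved in both directions at 6 h, and 2 explanations were weighed. More priming on RNA without a poly(A) tail could raise transfer RNAs. It would raise nuclear small RNAs too, whose median was 0.294 over 40 genes (notch 0.236, interquartile range 0.949), with 3 called higher and 1 lower. A 7SK gene rose by 2.83, past the smallest tRNA rise (2.02). The set holds pseudogene copies (as RNU4-62P), so its median cannot test priming. Loss of transcripts with distance from the promoter of the heavy strand would give a negative correlation of order and fold change. Over 12 mRNAs it was 0.189 (one-sided permutation p = 0.73), which argues against it among the mRNAs. The test left out the transfer and ribosomal RNAs. At the start of the order MT-TF (3.24), MT-RNR1 (1.85), MT-TV (3.54) and MT-TL1 (4.72) rose, and MT-RNR2 (0.48) was not called. Near its end MT-ND5 (1.53) rose too. Such a loss over all transcripts of the strand therefore stays open.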
